A study of Rattus norvegicus with 12 samples.

How the data were processed

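Liver RNA of 12 Sprague Dawley rats, 4 fed naproxen, 4 fed NO-naproxen and 4 fed a control diet for 7 days, was measured on Affymetrix whole-transcript arrays, 1 array per rat, after ribosomal RNA removal and biotin labelling, per the labels' protocols. The deposited values are probe set intensities on a linear scale, 19418 for each of 12 arrays. They came from Affymetrix Expression Console 1.1.1 and build rn4, per the submitters' processing notes. The summary method and the normalization of the deposited intensities are not given in the sources used here. Array medians between 89.8 and 118 and differing spreads show that the columns do not share one distribution. The tests were planned for log2 values. As the deposited intensities were linear and reached below 1, 16 was added before log2, so fold changes are on the log2(intensity + 16) scale and understate the change of dim probe sets. Between 5.87% and 11.1% of the values per array were under 16.

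Of the probe sets, 13327 carried 1 gene symbol in the platform annotation, 620 several and 5471 none, and only those with 1 symbol were named. Through Entrez identifiers 13232 probe sets were matched to the RefSeq gene table, and 0 symbols changed. A gene with several probe sets, which was so for 102 genes, was represented by the one with the highest mean over all arrays. No coordinates are given, since the gene table and the arrays use different builds. Background was judged from 970 probe sets of olfactory and vomeronasal receptors: a mean at or below their 95th percentile, 6.44 on the log2 scale, was called within the olfactory receptor range, which held 38.0% of all probe sets.

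Groups came from the labels, and the replicate numbers from the sample titles. All 12 arrays entered 1 fit of limma 3.58.1 (lmFit and eBayes in R 4.3.3, 2-sided) with the 3 diets as groups and no other term, and each pair of diets was a contrast. Probe sets were called at an adjusted p under 0.05 (Benjamini-Hochberg over all probe sets). The study's criterion, an unadjusted p under 0.05 and a change of at least 1.5-fold, was applied to the same fit, since the test behind it is not given in the sources used here. Of 36 gene lists, 35 with at least 5 measured genes were tested with camera (preset correlation 0.01, Benjamini-Hochberg over lists), with camera's estimated correlation, with fry in its directional and mixed forms, and with an exact permutation test of the list's mean per array. The fit, the tests, the lists, most alternatives and the rule for naming genes were set before the data were examined.

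Genes were named by that rule: for each comparison, up to 10 in each direction with the largest change among those past the adjusted threshold with separate groups, or, with fewer than 5, the genes with the smallest p among those past the study's criterion with separate groups; up to 4 members with the smallest p of each list described; and 11 genes tied to the drugs or to liver responses. The rule left open which lists are described. Those past camera or the mixed test of fry were taken, and the lists for the clock, cholesterol, the cell cycle, the acute phase, prostaglandins and nitric oxide were added after their values were seen.

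Alternatives were a trended and robust spread, only the groups compared, quantile normalization, median centring, a filter on the dimmest 30% of probe sets, 1 probe set per gene, array weights, a fold of at least 2 for the criterion, the mean of a gene's probe sets for lists, controls split 2 against 2 for the correlation, the replicate number as a block and each array left out in turn. Added constants of 1 and 64, the array's interquartile range as a covariate, and leaving out the 2 arrays of narrowest spread were chosen after seeing the data. The replicate numbers came from the titles, and no label ties a number to a shared litter or day.

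The limma step was tested on simulated data drawn from the measured means and spreads of the 19418 probe sets, with 200 changed. For naproxen against control it recovered 67.2% of 67 probe sets changed by 1 log2 unit, 92.5% of 67 changed by 1.5 and 98.5% of 66 changed by 2. For NO-naproxen against control the shares were 55.2%, 92.5% and 98.5%, and for NO-naproxen against naproxen 61.2%, 92.5% and 98.5%. Among unchanged probe sets of these simulations it called 11, 6 and 5 in the 3 comparisons in that order. With no change simulated it called 0 probe sets in each comparison, with 5.05%, 5.26% and 5.18% at an unadjusted p under 0.05. A shift of 0.3 in the 35 cell cycle genes was called by camera in each comparison and no other list was. The simulated probe sets were drawn independently, without correlation between genes and without differences in spread between arrays. The runs therefore do not show how often probe sets or lists are called falsely in the measured data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.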

Results

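The livers of 12 Sprague Dawley rats were profiled on whole-transcript expression arrays after 7 days on 1 of 3 diets, with 4 rats per diet. One group ate a diet with naproxen at 400 mg/kg, a nonsteroidal anti-inflammatory drug that inhibits both cyclooxygenases. Another ate NO-naproxen at 550 mg/kg, a derivative of naproxen that carries a nitric oxide-donating group. The controls ate the diet without drug. Each array gave 19418 probe sets, and the median intensity per array lay between 89.8 and 118. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.21, and the median 95% interval reached 0.44 to either side. The arrays differed in the spread of their signals, with an interquartile range of 2.10 ± 0.19 log2 units in controls, 2.34 ± 0.16 with naproxen and 2.36 ± 0.23 with NO-naproxen (SD, n = 4). These differences from control did not pass the 2-sided exact permutation test (p = 0.114 and p = 0.143, both 0.429 after Benjamini-Hochberg adjustment over 9 tests). The first principal component held 46.2% of the variance and followed this spread over the 12 arrays, with Pearson's r = 0.971 and Spearman's rho = 0.993. Both had a permutation p of 1e-05, the smallest that the resamples can give, and r was 0.979 without the 2 arrays farthest from the median.

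**Figure D1:**
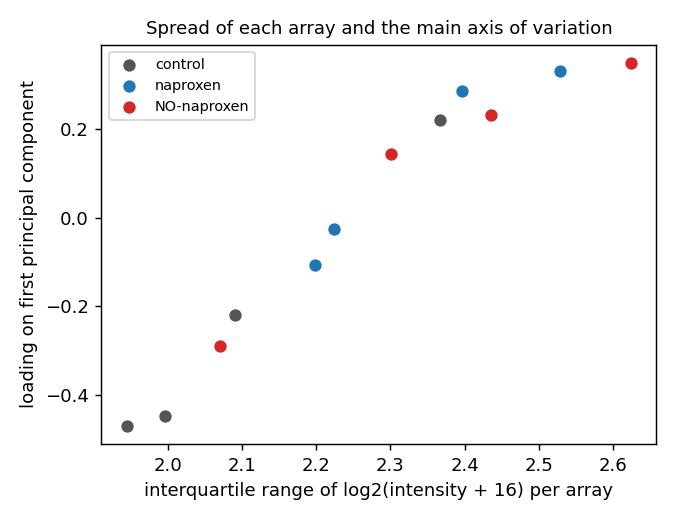
Loading on the first principal component (y axis, no unit) against the interquartile range of log2(intensity + 16) (x axis, log2 units), 1 point per array, coloured by diet. The 2 arrays with the narrowest spread are both controls, the narrowest at 1.94, and r over the 12 arrays is 0.971.

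One of the 2 comparisons the series design names is that of naproxen with control. Genes of the cell cycle had a mean log2 fold change of 0.28 in livers of naproxen-fed rats over 35 measured genes, 23 of them above 0. Camera called this list at its preset correlation (adjusted p = 0.00119), but not with the estimated correlation of 0.205 (adjusted p = 0.966). The directional form of fry did not call it either (adjusted p = 0.547). Among the cell cycle genes, the proliferation marker Mki67 (Entrez Gene 291234) measured 7.11 ± 0.20 on the log2 scale with naproxen against 6.01 ± 0.44 in controls (SD, n = 4), a 2.15-fold difference. Its mean over all arrays lay just above 6.44, the bound of the olfactory receptor range, and its control mean below that bound. Genes of the circadian clock differed in both directions, with the clock repressor Nr1d1 (Entrez Gene 252917) at 9.39 ± 0.40 against 7.67 ± 0.56 and Per2 (Entrez Gene 63840) at 6.76 ± 0.42 against 8.18 ± 0.69 (SD, n = 4). Cyp7a1 (Entrez Gene 25428), the rate-limiting enzyme of bile acid synthesis, had a log2 fold change of -1.06 ± 0.25 (SE), with all 4 naproxen arrays below all 4 control arrays. No single probe set passed the limma test after Benjamini-Hochberg adjustment over all 19418, so the values of single genes are given here as measured differences. The smallest adjusted p was 0.245, and 2458 probe sets had an unadjusted p under 0.05. These were 12.7% of all, against 5.05% in simulated data with no change. The share was 5.63% with the arrays' spread as a covariate.

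The exact permutation test of the cell cycle list's mean per array gave p = 0.0571. No member passed over all probe sets, and 6 higher and 1 lower passed when adjusted over the list alone. Of the higher ones, Mki67 had a log2 fold change of 1.11 ± 0.30 (SE), the DNA topoisomerase Top2a of 1.13 ± 0.32, the cytokinesis regulator Ect2 of 1.04 ± 0.25 and the spindle factor Tpx2 of 0.88 ± 0.22. The lower one, named after its values were seen, was Ccne1, a cyclin of the entry into S phase, at -0.59. Markers of Kupffer cells and macrophages, the phagocytes of the liver, had a mean of 0.20 log2 units, with 24 of 25 log2 fold changes above 0. Camera called them at the preset correlation (adjusted p = 0.00527), but not with the estimated one of 0.418 (adjusted p = 0.966). Vsig4, a complement receptor of Kupffer cells, had a log2 fold change of 0.42 ± 0.19, Ptprc of 0.41 ± 0.27, Ctss of 0.38 ± 0.26 and the receptor of colony stimulating factor, Csf1r, of 0.35 ± 0.21. The call of the Kupffer cell list ended after quantile normalization (adjusted p = 0.0808) and without naproxen replicate 2 (adjusted p = 0.087) (range over 19 alternatives run with the preset correlation 0.000215 to 0.359). It also ended without the 2 arrays of narrowest spread, both controls, where the mean was 0.069 (adjusted p = 0.359). The exact permutation test of this list's mean per array gave p = 0.143. The cell cycle list passed in all 19 of these alternatives, which share the preset correlation, with adjusted p from 1.22e-07 to 0.0483.

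**Figure D2:**
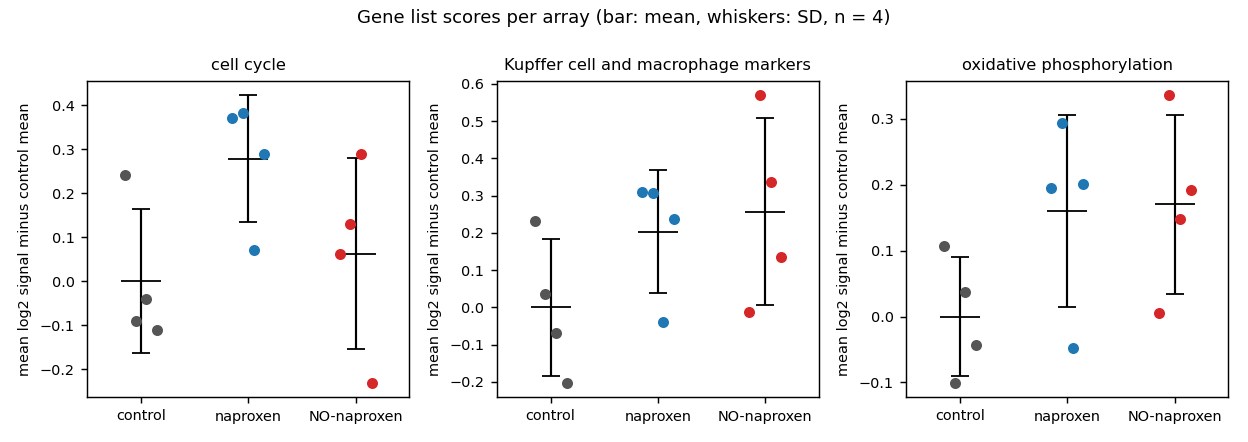
Mean log2(intensity + 16) of the genes of 3 lists on each array, minus the control mean (y axis, log2 units), by diet (x axis); points are arrays, bars are means and whiskers are SDs of 4 arrays. The cell cycle mean with naproxen lies 0.28 above that of controls, against 0.06 with NO-naproxen.

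Genes of oxidative phosphorylation had a mean log2 fold change of 0.16 with naproxen against control, with 43 of 49 above 0. Camera called this list at the preset correlation (adjusted p = 0.00161), but not with an estimated one (adjusted p = 0.966). The complex I subunits Ndufv2, Ndufs1 and Ndufb8 had log2 fold changes of 0.52 ± 0.20, 0.33 ± 0.16 and 0.40 ± 0.18 (SE), and cytochrome c, Cycs, one of 0.51 ± 0.25. Cytochrome P450 genes of drug metabolism and their regulators had a mean of 0.19, with 14 of 24 log2 fold changes above 0. For these too camera passed at the preset correlation (adjusted p = 0.0378), but not with an estimated one (adjusted p = 0.966). In that list the receptors Nr1i3, known as CAR, and Ahr had log2 fold changes of 0.86 ± 0.27 and 0.61 ± 0.22, and the enzymes Cyp3a2 and Cyp2a3 of 0.85 ± 0.32 and 0.60 ± 0.20. Its mean per array gave the smallest p that an exact permutation test of 4 against 4 can give, p = 0.0286, which did not pass adjustment over the lists. The same exact permutation test gave p = 0.114 for oxidative phosphorylation, 0.143 for the endothelial and 0.0571 for the stellate list below. Camera at the preset correlation also called markers of endothelial cells (mean 0.19, adjusted p = 0.0183) and of stellate cells and fibrosis (mean 0.14, adjusted p = 0.0385). Neither passed with the estimated correlations of 0.340 and 0.165 (adjusted p = 0.966 for both). The sinusoidal genes Oit3 and Clec4g measured 0.42 ± 0.15 and 0.54 ± 0.22, the vascular receptor Flt4 0.40 ± 0.17 and Wnt2 -0.36 ± 0.19 (log2 fold change, SE). Of the stellate list, the pericyte gene Rgs5 had a log2 fold change of 0.71 ± 0.20, the matrix genes Dcn and Col4a1 of 0.52 ± 0.24 and 0.37 ± 0.16, and Thy1, in the olfactory receptor range, of -0.48 ± 0.22. The spread of the arrays was 0.24 log2 units wider with naproxen. With that spread as a covariate, added after seeing the data, the endothelial and stellate means were 0.059 and 0.042 (adjusted p = 0.341 and 0.373). The oxidative phosphorylation and cytochrome P450 means were then 0.17 and 0.18 (adjusted p = 2.96e-06 and 0.00354), and 8 lists passed. Without the 2 arrays of narrowest spread the endothelial and stellate means were 0.062 and 0.061 (adjusted p = 0.359 for each). With array weights the cytochrome P450, endothelial and stellate lists missed the threshold (adjusted p = 0.0698 for each), as they did without dim probe sets (adjusted p = 0.0601, 0.0601 and 0.134). The oxidative phosphorylation, cytochrome P450 and stellate lists missed the threshold after quantile normalization (adjusted p = 0.208, 0.0808 and 0.119). Without naproxen replicate 2 all 4 lists missed it (adjusted p = 0.087, 0.116, 0.0927 and, for the endothelial list, 0.0656), which left 1 list past the threshold. The oxidative phosphorylation and cytochrome P450 lists also missed it without control replicate 2 (adjusted p = 0.0562 and 0.119), both the endothelial list, with a mean of 0.12, and the stellate list without control replicate 4 (adjusted p = 0.068 for each), and the stellate list without naproxen replicate 3 or control replicate 3 (adjusted p = 0.19 and 0.0866). Over the 19 alternatives the adjusted p ranged from 2.96e-06 to 0.208 for oxidative phosphorylation, 0.00354 to 0.119 for cytochrome P450, 0.00309 to 0.359 for endothelial and 0.00835 to 0.373 for stellate genes.

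The mixed test of fry, which asks whether genes of a list change in either direction, passed for 4 lists with naproxen. For the circadian clock its adjusted p was 0.0448, with 1 gene higher and 2 lower when adjusted over the list alone, and camera did not pass (adjusted p = 0.415; mean -0.096, 0.019 after median centring). Without each control array in turn the unadjusted mixed p ranged from 7.4e-06 to 0.0532, the highest without control replicate 4. Nr1d1 had a log2 fold change of 1.72 ± 0.42, Per2 of -1.42 ± 0.31, Cry1 of -0.74 ± 0.25 and the clock activator Npas2 of 0.41 ± 0.22 (SE). Genes of the PPAR-alpha and fatty acid oxidation list changed by the mixed test (adjusted p = 0.0231). Their mean was 0.095, and camera did not pass (adjusted p = 0.0934). The exact permutation test of the mean per array gave p = 0.143. At an unadjusted p under 0.05, 5 members were higher and 1 lower, and none passed when adjusted over the list alone. The rate-limiting enzyme of fatty acid import into mitochondria, Cpt1a, measured 0.58 ± 0.16, Decr1 0.49 ± 0.17, Acot2 0.43 ± 0.17 and the peroxisome gene Pex11a 0.42 ± 0.16 (log2 fold change, SE), with naproxen and control arrays not overlapping for any of the 4. In the list of hepatocyte markers (mixed adjusted p = 0.00944) the tryptophan-degrading enzyme Tdo2 had a log2 fold change of 0.62 ± 0.15, Tat of -0.42 ± 0.19, the transcription factor Hnf4a of -0.33 ± 0.17 and Vtn of -0.15 ± 0.16. Camera did not pass for this list (adjusted p = 0.905, mean -0.025). Of its 17 members, 15 had an unadjusted p of 0.05 or more, and 1 passed when adjusted over the list alone. The cell cycle list passed this test as well (adjusted p = 0.0321).

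**Figure D3:**
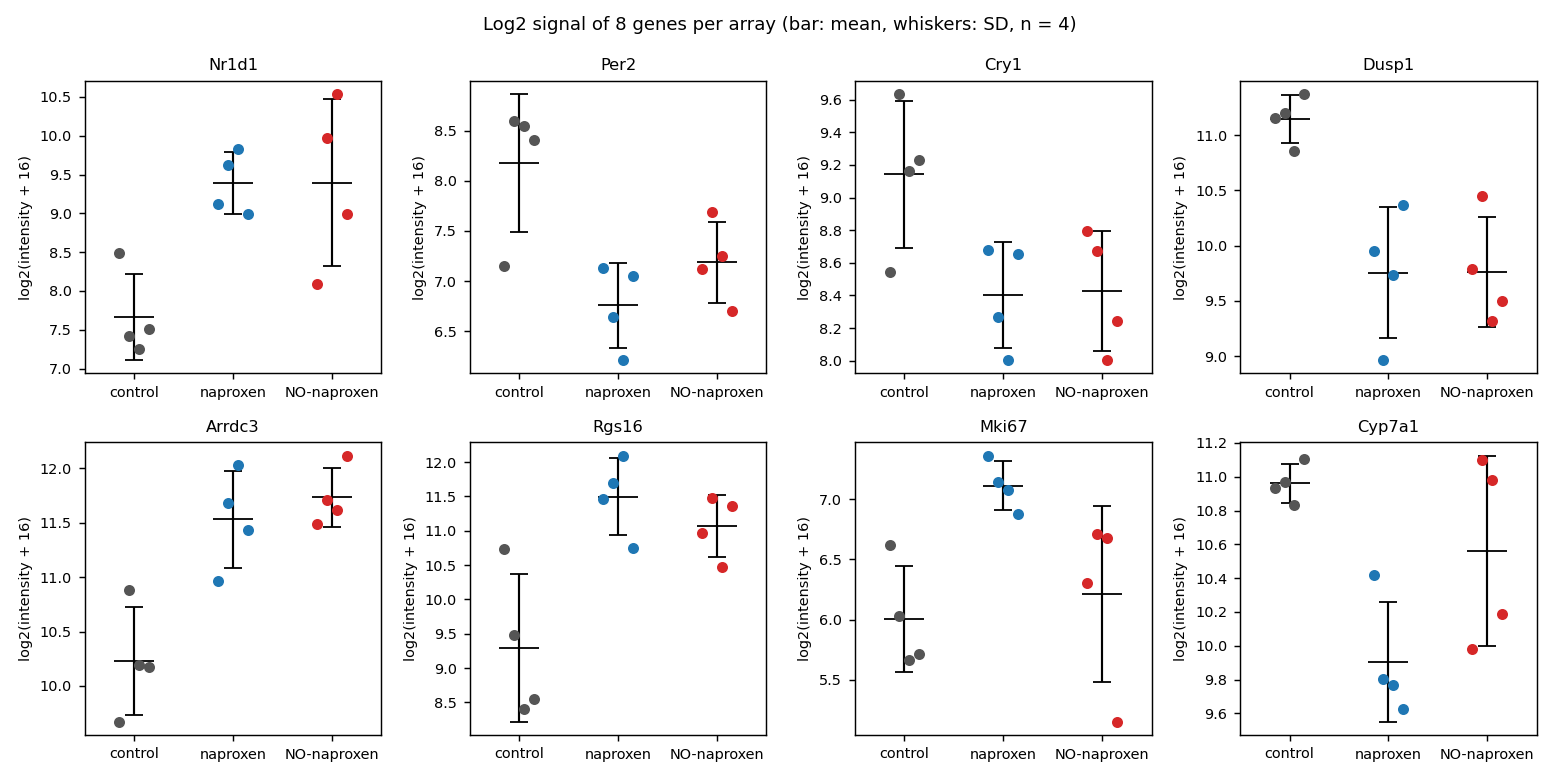
Log2(intensity + 16) of 8 genes on each array (y axis, log2 units, scaled per gene and not starting at 0) by diet (x axis); points are arrays, bars are means and whiskers are SDs of 4 arrays. Per2 measured 7.15 on control replicate 1 and 8.41 to 8.60 on the other controls, and all 4 naproxen arrays lay below all controls.

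By the study's own criterion, an unadjusted p under 0.05 and a change of at least 1.5-fold, 1135 probe sets differed between naproxen and control, 170 higher and 965 lower. They held 722 named genes, 124 higher and 598 lower. Of the lower probe sets, 51.7% had a mean signal within the range of olfactory receptor probe sets, whose genes serve the sense of smell, against 20.6% of the higher and 38.0% of all probe sets. Among genes with separate groups past this criterion but not past the adjusted threshold, those with the smallest p on the higher side were Rgs16, Arrdc3, Upp2, Hykk and Spink1. Rgs16, a regulator of G protein signalling, measured 2.20 ± 0.42 (log2 fold change, SE), the uridine phosphorylase Upp2 1.88 ± 0.39, Arrdc3 1.30 ± 0.26, Hykk 0.86 ± 0.19 and Spink1, in the olfactory receptor range, 0.85 ± 0.20. On the lower side stood Dusp1, a phosphatase of MAP kinases, with -1.39 ± 0.28, Per2 and Cyp7a1 as above, and 2 genes in the olfactory receptor range, Neto1 and Tex38, with -0.97 ± 0.23 and -0.78 ± 0.18. The arrays of the 2 groups did not overlap for 4.50% of probe sets, where chance gives 2.86%. The split between higher and lower was 371 to 603 after quantile normalization, 139 to 193 with the arrays' spread as a covariate and 463 to 483 after median centring, which moved the median log2 fold change of all probe sets from -0.03 to 0.08. Without naproxen replicate 3, control replicate 3 or control replicate 4 the count was 684, 600 or 574, and without naproxen replicate 4 or control replicate 2 it was 2122 or 2973. Without control replicate 1 or 2, 3 and 2 probe sets passed the adjusted threshold.

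Of the enzymes that naproxen inhibits, Ptgs1 had a log2 fold change of 0.26 ± 0.18 (SE) and Ptgs2 of -0.49 ± 0.23 in this comparison. In the prostaglandin and leukotriene list, which camera did not call (adjusted p = 0.874; mean -0.0055, median 0.02), the prostaglandin receptor Ptger4, in the olfactory receptor range, measured -0.97 ± 0.24 and passed when adjusted over the list alone, Ptger1 measured -0.44 ± 0.22 and the prostaglandin D synthase Hpgds 0.53 ± 0.24. The stress enzymes Hmox1 and Nqo1 had log2 fold changes of 0.40 ± 0.19 and 0.56 ± 0.18, and the nitric oxide synthases Nos2 and Nos3 of -0.56 ± 0.37 and -0.21 ± 0.15. In the acute phase list (camera, adjusted p = 0.798; mean 0.03, median -0.04) the interleukin 1 receptor antagonist Il1rn measured 0.83 ± 0.29, Il6r 0.62 ± 0.29, Stat3 0.37 ± 0.18 and F13b 0.21 ± 0.17. For the iron hormone Hamp, the protease inhibitor A2m and Cyp1a1, the last 2 in the olfactory receptor range, the 95% intervals of the log2 fold change were -0.76 to 0.22, -0.82 to 0.59 and -0.67 to 0.36. The cholesterol synthesis list had a mean of -0.11, and 0.0022 after median centring (camera, adjusted p = 0.293; range over the alternatives 0.000142 to 0.901). Without naproxen replicate 1 the mean was -0.20 (adjusted p = 0.0305) and without naproxen replicate 2 it was -0.0091 (adjusted p = 0.901). It was -0.25 with the arrays' spread as a covariate and -0.16 without the 2 arrays of narrowest spread (adjusted p = 0.000142 and 0.0429). In that list Msmo1 measured -0.41 ± 0.18, Tm7sf2 -0.32 ± 0.18, Mvd -0.32 ± 0.19 and Ggps1 0.52 ± 0.25.

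The other comparison the series design names is that of NO-naproxen with control. Genes of cholesterol synthesis and uptake had a mean log2 fold change of -0.16 over 18 measured genes, 4 of them above 0. Camera called this list at the preset correlation (adjusted p = 0.0382), but not with the estimated one of 0.334 (adjusted p = 0.96). Squalene epoxidase, Sqle (Entrez Gene 29230), measured 8.97 ± 0.41 with NO-naproxen against 9.70 ± 0.18 in controls, and Msmo1 (Entrez Gene 140910) measured 10.71 ± 0.29 against 11.30 ± 0.14 (SD, n = 4). Kupffer cell and macrophage markers had a mean of 0.26 (0.15 without NO-naproxen replicate 2, where the call ended), and genes of oxidative phosphorylation one of 0.17. Camera called both at the preset correlation (adjusted p = 0.0176 and 0.0382), but neither with an estimated one (adjusted p = 0.96 for both). Of the clock genes, Nr1d1 measured 9.40 ± 1.08 and Per2 7.19 ± 0.40 (SD, n = 4), against 7.67 ± 0.56 and 8.18 ± 0.69 in controls. No probe set passed the adjusted threshold in limma, where the smallest adjusted p was 0.468 and 2011 probe sets had an unadjusted p under 0.05. These were 10.4% of all, against 5.26% in simulated data with no change. The share was 3.53% with the arrays' spread as a covariate.

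Of the 18 cholesterol genes, 2 passed when adjusted over the list alone, both lower and none over all probe sets: Sqle with a log2 fold change of -0.73 ± 0.21 (SE) and Msmo1 with -0.59 ± 0.18. Mvd, an enzyme of the mevalonate pathway, measured -0.43 ± 0.19 and Ggps1 0.56 ± 0.25. Of the 25 Kupffer cell and macrophage markers 22 had a log2 fold change above 0, with Ptprc at 0.67 ± 0.27, Csf1r at 0.50 ± 0.21, Vsig4 at 0.44 ± 0.19 and Aif1 at 0.38 ± 0.21. Of the 49 oxidative phosphorylation genes 43 did, with the cytochrome c oxidase subunit Cox7b at 1.09 ± 0.27, Ndufv2 at 0.71 ± 0.20, Atp5me at 0.39 ± 0.18 and Ndufs1 at 0.32 ± 0.16. Exact permutation tests of the means per array gave p = 0.114 for the cholesterol, 0.171 for the Kupffer cell and 0.0857 for the oxidative phosphorylation list. Markers of endothelial cells had a mean of 0.21, with 15 of 16 above 0, and those of stellate cells and fibrosis one of 0.14, with 18 of 24 above 0. Neither was called (camera, adjusted p = 0.106 and 0.262). After quantile normalization the Kupffer and oxidative phosphorylation calls ended, at means of 0.15 and 0.044 (adjusted p = 0.273 and 0.881; ranges over the alternatives 3.84e-06 to 0.474 and 7.24e-05 to 0.881). All 3 calls ended with array weights (adjusted p = 0.363 for cholesterol, 0.474 for the Kupffer cell and 0.716 for the oxidative phosphorylation list, and 0 lists passed). With the replicate number as a block 1 list passed, and the cholesterol and oxidative phosphorylation calls ended (adjusted p = 0.0851 and 0.08). The cholesterol call ended after median centring (mean -0.093, adjusted p = 0.0848), the Kupffer call without the 2 arrays of narrowest spread (mean 0.12, adjusted p = 0.382) and the oxidative phosphorylation call without dim probe sets (adjusted p = 0.112). All 3 calls ended too without NO-naproxen replicate 3 (adjusted p = 0.279 for cholesterol and 0.25 for the others) or control replicate 2 (adjusted p = 0.28, 0.0809 and 0.214). The cholesterol call also ended without NO-naproxen replicate 4 (adjusted p = 0.0621; range 2.6e-11 to 0.363), the Kupffer call without NO-naproxen replicate 2 (mean 0.15, adjusted p = 0.0901) and the oxidative phosphorylation call without NO-naproxen replicates 2 or 4 (adjusted p = 0.104 and 0.239). Without NO-naproxen replicate 1, 5 lists passed.

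In the clock list Nr1d1 had a log2 fold change of 1.73 ± 0.42 (SE) and Per2 of -0.99 ± 0.31, and these 2 passed when adjusted over the list alone. Per1 measured 1.01 ± 0.41 and Cry1 -0.72 ± 0.25. The list passed neither camera (adjusted p = 0.764; mean 0.056, median -0.049; mean -0.05 after quantile normalization and -0.059 without NO-naproxen replicate 2) nor the mixed test of fry (adjusted p = 0.214). The cell cycle list did not pass either (camera, adjusted p = 0.944; mean 0.06, and -0.013 without NO-naproxen replicate 3), with 2 members higher and 2 lower at an unadjusted p under 0.05: Tyms at 0.59 ± 0.22, Tpx2 at 0.56 ± 0.22, Cdc6 at -0.38 ± 0.16 and Ccne1 at -0.40 ± 0.18.

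By the study's criterion 738 probe sets differed between NO-naproxen and control, 346 higher and 392 lower, and they held 500 named genes, 275 higher and 225 lower. Of the lower probe sets, 58.4% lay within the olfactory receptor range, against 11.3% of the higher and 38.0% of all probe sets. The arrays did not overlap for 3.35% of probe sets, where chance gives 2.86%. The genes with the smallest p and separate groups on the higher side were Arrdc3 with a log2 fold change of 1.50 ± 0.26 (SE), Depp1, a gene induced by fasting, with 1.39 ± 0.31, Spink1, in the olfactory receptor range, with 0.87 ± 0.20, Hykk with 0.84 ± 0.19 and Sap130 with 0.65 ± 0.16. On the lower side were Dusp1 with -1.38 ± 0.28 and Csad, an enzyme of taurine synthesis, with -1.18 ± 0.27, and, in the olfactory receptor range, Or7d12 with -0.82 ± 0.18, Cib2 with -0.84 ± 0.21 and Or51f5 with -0.87 ± 0.23. None passed the adjusted threshold (adjusted p = 0.468 for each in limma). The split did not keep its direction throughout. After median centring it was 632 higher to 266 lower, and with the arrays' spread as a covariate 144 to 92. It was 324 to 212 without dim probe sets, 280 to 241 with 1 probe set per gene, 103 to 51 with an added constant of 64 and 139 to 76 without the 2 arrays of narrowest spread. Without NO-naproxen replicate 4 it was 688 to 271, without control replicate 1 529 to 356 and without control replicate 3 234 to 176. The count was 429, 284, 410 and 338 without NO-naproxen replicates 1 or 2 or control replicates 3 or 4, and 2458 and 2570 without NO-naproxen replicate 3 or control replicate 2. Without control replicate 2, 4 probe sets passed the adjusted threshold.

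For the targets of the drug, Ptgs1 had a log2 fold change of 0.38 ± 0.18 (SE) and Ptgs2 of -0.41 ± 0.23 with NO-naproxen. In their list (camera, adjusted p = 0.704) Cyp4f6 measured 0.47 ± 0.20, Hpgds 0.48 ± 0.24 and Ptgdr2, in the olfactory receptor range, -0.40 ± 0.22. The nitric oxide and cyclic GMP list did not pass (camera, adjusted p = 0.704). Its members with the smallest p were both subunits of soluble guanylate cyclase, the receptor of nitric oxide, Gucy1a1 with 0.82 ± 0.29 and Gucy1b1 with 0.46 ± 0.23, Prkg2, in the olfactory receptor range, with -0.67 ± 0.27 and the phosphodiesterase Pde3b with 0.46 ± 0.22. The synthases Nos2 and Nos3 measured -0.19 ± 0.37 and -0.11 ± 0.15, and Nos2 measured 0.021 without control replicate 3. Hmox1 had a log2 fold change of 0.56 ± 0.19, with all 4 NO-naproxen arrays above all 4 controls, and Nqo1 one of 0.34 ± 0.18. Of the acute phase list (camera, adjusted p = 0.808) Il1rn measured 0.89 ± 0.29, Il6r 0.67 ± 0.29, Stat3 0.35 ± 0.18 and Lcn2, in that range too, -0.41 ± 0.27. Cyp7a1 measured -0.40 ± 0.25. The 95% intervals for Hamp and, in that range, A2m and Cyp1a1 were -0.48 to 0.51, -1.12 to 0.29 and -0.53 to 0.50.

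The 2 compounds were also compared with each other, at doses in the diet that differed, 550 against 400 mg/kg. Cell cycle genes were lower on average with NO-naproxen than with naproxen, with a mean log2 difference of -0.22. Camera called this list at the preset correlation (adjusted p = 6.94e-11), but not with the estimated one of 0.205 (adjusted p = 0.626). Without NO-naproxen replicate 4 the mean difference was -0.12, still past camera's threshold at the preset correlation (adjusted p = 6.57e-06; range over the alternatives 4.15e-12 to 6.57e-06). On that array Mki67 measured 5.15, against 6.30 to 6.71 on the other NO-naproxen arrays. Mki67 measured 6.21 ± 0.73 with NO-naproxen against 7.11 ± 0.20 with naproxen (SD, n = 4), Ect2 had a log2 fold change of -0.61 ± 0.25 (SE), Kif20a of -0.43 ± 0.18 and Ccnb1 of -0.58 ± 0.25. The NO-naproxen mean of Mki67 lay below 6.44, the bound of the olfactory receptor range. No member passed over all probe sets or when adjusted over the list alone, 6 were lower and none higher at an unadjusted p under 0.05, and 9 of 35 log2 fold changes lay above 0. The exact permutation test of the list's mean per array gave p = 0.114. Kupffer cell and macrophage markers differed by a mean of 0.05 between the compounds (camera, adjusted p = 0.981). Heat shock genes were higher with NO-naproxen by a mean of 0.22, with 14 of 16 log2 differences above 0 (camera, adjusted p = 0.0338; adjusted p = 0.994 with an estimated correlation), with no member at an unadjusted p under 0.05. The exact permutation test of its mean per array gave p = 0.286. Minus the control mean, that list lay at 0.44, 0.51, 0.08 and -0.10 on NO-naproxen replicates 1 to 4 and at 0.26, -0.10, -0.22 and 0.10 on naproxen replicates 1 to 4. The chaperone Hsp90ab1 measured 0.44 ± 0.26, Hsph1 0.38 ± 0.23, the co-chaperones Bag3 and Stip1 0.34 ± 0.21 and 0.34 ± 0.24. This call ended without NO-naproxen replicates 1 or 2 or naproxen replicates 2, 3 or 4 (adjusted p = 0.195, 0.201, 0.179, 0.0723 and 0.108; range over the alternatives 0.000832 to 0.201). The mean was 0.13 without NO-naproxen replicate 2 and 0.15 without naproxen replicate 3. The call ended also with an added constant of 1 and with the arrays' spread as a covariate (adjusted p = 0.0728 and 0.0945). Without NO-naproxen replicate 2, 4 lists passed, and the cholesterol list passed without that array or without naproxen replicate 2 (adjusted p = 0.0156 and 1.72e-05; range 1.72e-05 to 0.839).

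No probe set differed between the compounds in limma after adjustment (smallest adjusted p 1.00). At an unadjusted p under 0.05, 373 did, which is 1.92% of them, and 111 passed the study's criterion, 83 higher and 28 lower with NO-naproxen. Of these, 74.7% and 75.0% lay within the olfactory receptor range. After quantile normalization that split was 51 to 46 and after median centring 55 to 46. The count was 197 without naproxen replicate 1, 181 without naproxen replicate 2, 331 without naproxen replicate 4 and 296 without NO-naproxen replicate 3. Arrays of the compounds did not overlap for 1.17% of probe sets, below the 2.86% that chance gives. A difference that misses the threshold does not show that the compounds act alike, since the median interval reached 0.44 log2 units to either side. For Cyp7a1 the log2 difference was 0.66 ± 0.25 (SE), with a 95% interval of 0.13 to 1.18 and an adjusted p of 1.00. The intervals were -0.24 to 0.56 for Hmox1, -0.60 to 0.15 for Nqo1, -0.27 to 0.50 for Ptgs1, -0.40 to 0.58 for Ptgs2, -0.42 to 1.16 for Nos2, -0.22 to 0.42 for Nos3, -0.21 to 0.77 for Hamp, -1.01 to 0.40 for A2m and -0.38 to 0.66 for Cyp1a1, the last 2 in the olfactory receptor range. In the nitric oxide and cyclic GMP list (camera, adjusted p = 0.672) Pde3b measured 0.31 ± 0.22, the arginine transporter Slc7a1 0.41 ± 0.30 and, in that range, Pde5a 0.36 ± 0.24 and Prkg2 -0.51 ± 0.27. Genes with the smallest p and separate groups were, on the higher side, Dffa with 0.68 ± 0.17 and Cdk2ap2 with 0.60 ± 0.19, and Tex38, Fpr1 and Gtsf1l in the olfactory receptor range with 0.65 ± 0.18, 0.66 ± 0.23 and 0.78 ± 0.27. On the lower side were Mki67 with -0.90 ± 0.30 and 4 genes in that range, Drd1, Or52n2b, Or5p4 and Or4x13, with -0.83 ± 0.22, -0.73 ± 0.21, -0.62 ± 0.19 and -0.65 ± 0.21.

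The fold changes of both treatments against control correlated across probe sets (r = 0.826; probe sets are not independent replicates). Both were taken against the same 4 control arrays, and simulated groups with no change gave r = 0.498. With the controls split 2 against 2 the observed r was 0.333 to 0.540 (mean 0.463). No array is shared then, so the simulated 0.498 is not the reference for this value. The covariance was 0.0885 against a simulated 0.0304, a difference of 0.0581, and with split controls it was 0.0576. Both steps take the scatter of the shared controls off the observed covariance, so the closeness of 0.0581 and 0.0576 adds no separate support. Neither removes the differences in spread between arrays. Of the probe sets past the study's criterion, 83 were higher in both comparisons, where independent lists give 3.03 and simulated unchanged groups 31.5, and 200 were lower in both, where these give 19.5 and 31.0. None passed in opposite directions. That would need the 2 treatments to lie at least 1.5-fold to either side of the same controls. The simulated probe sets were drawn independently, without the differences in spread between arrays. The overlap was not counted over regroupings of the measured arrays, so its excess over the simulated counts may hold that structure. The genes named above that passed the criterion in both follow, with the log2 fold change with naproxen first and NO-naproxen second. Lower were Dusp1 (-1.39 and -1.38), Per2 (-1.42 and -0.99), Csad (-1.07 and -1.18), Cry1 (-0.74 and -0.72) and, in the olfactory receptor range, Neto1 (-0.97 and -0.70), Or7d12 (-0.67 and -0.82) and Or51f5 (-0.63 and -0.87). Higher were Rgs16 (2.20 and 1.77), Upp2 (1.88 and 1.74), Nr1d1 (1.72 and 1.73), Arrdc3 (1.30 and 1.50), Depp1 (1.22 and 1.39) and Nr1i3 (0.86 and 0.67). Higher too were Hykk (0.86 and 0.84), Cyp3a2 (0.85 and 1.13), Il1rn (0.83 and 0.89), Ahr (0.61 and 0.63) and, in that range, Spink1 (0.85 and 0.87).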

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

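The count of clock genes per control rat, the shares of a change kept without 1 array or after quantile normalization, the tests of the array scale, of signal near background, of single naproxen arrays and of Kupffer cells, and the count of groupings for the correlation were chosen only after the results were seen. In groups of 4, an array was singled out when its gap to the nearest other took most of the group's range. This held in 24 of 420 groups checked, or 5.71%, and chance gives about 1 in 20. In the gap's share of the range, genes set apart by a control array were Per2 (0.869) and Upp2 (0.924), Cdk2ap2 (0.844) and Mvd (0.858), all on control replicate 1, Tdo2 (0.845) on control replicate 2 and Drd1 (0.877) on control replicate 4. Among naproxen arrays, replicate 1 stood apart for Tat (0.906) and Gucy1b1 (0.865) and replicate 3 for Ndufs1 (0.854). Among NO-naproxen arrays, replicate 1 stood apart for Cdc6 (0.885) and Ctss (0.919), replicate 2 for Decr1 (0.834), Hykk (0.872) and Or51f5 (0.88), replicate 3 for Lcn2 (0.855) and Nos2 (0.921), and replicate 4 for Dffa (0.856), Hsph1 (0.903) and Or52n2b (0.94). Of the list means, the cytochrome P450 list stood apart on naproxen replicate 3 (0.859), heme and iron handling on control replicate 4 (0.913), the urea cycle on control replicate 2 (0.931) and the unfolded protein response on NO-naproxen replicate 4 (0.904). The median of the olfactory receptor probe sets stood apart on NO-naproxen replicate 3 (0.894), at 5.26 against 5.04 to 5.07.

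Clock genes differed between naproxen and control by the mixed test. After quantile normalization the unadjusted mixed p was 0.00252, which argues against unequal distributions of the arrays as the whole cause. Changes tied to the arrays' spread can outlast that step: 974 probe sets passed the criterion with naproxen after it, against 332 with the spread as a covariate. The mixed test was not run with that covariate, so the spread of the arrays stays open. Without any 1 control, at least 88.3% of the summed changes of the clock genes was kept (95% interval over resampled genes 74.2% to 97.6%). This argues against a single control array as the whole cause. Each gene's direction was taken from all arrays, and the interval is over genes that change together, not over rats. The mixed p, the test set beforehand, reached 0.0532 without control replicate 4. The loss of an array can raise a p with the changes kept. On control replicate 1, 10 of 16 clock genes lay nearer the naproxen mean than the mean of the other controls, against 7, 4 and 3 on the others. Without that rat 119% of the summed changes was kept (95% interval over resampled genes 103% to 137%). That rat therefore narrowed the difference between naproxen and control, which argues against it as the cause. The labels give neither time of collection nor feeding. A part of either in other rats, or between whole diet groups, therefore cannot be told apart from an effect of the drug.

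Of the probe sets past the study's criterion with naproxen, 85.0% were lower. Signal near background is argued against as the whole cause, since the share was 80.6% without the dimmest probe sets. With an added constant of 64, which shrinks the changes of dim probe sets most, it was 73.3% (51 higher and 140 lower). A part from signal near background therefore stays open. The scale of the arrays is a candidate explanation. The lower share was 61.9% after quantile normalization and 51.1% after median centring. It was 58.1% with the arrays' spread as a covariate and 60.8% without the 2 arrays of narrowest spread. With the spread as a covariate, 49.9% of the mean change of the 965 lower probe sets was kept (95% interval over the arrays 3.49% to 96.4%). These probe sets were chosen as lower in the same data, so the size of this part stays open. One naproxen array is a candidate explanation too, since the lower share was 61.0% without naproxen replicate 3. An effect of naproxen itself was not tested apart from these.

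Cell cycle genes were higher with naproxen than with NO-naproxen. Unequal distributions of the arrays are argued against as the whole cause, since 122% of the mean difference was kept after quantile normalization (95% interval over resampled genes 113% to 140%). That interval is over genes that change together, not over rats. Changes tied to the arrays' spread can outlast this step. The mean interquartile ranges of the compounds differed by 0.021 log2 units, so there was little difference in spread to remove. A single array stays open: without NO-naproxen replicate 4, 54.8% was kept (20.7% to 71.8%), and camera's p at its preset correlation, the test set beforehand, does not decide because with an estimated correlation the list missed the threshold. More Kupffer cells with naproxen stay open, though the mean of their markers was 0.0534 higher with NO-naproxen than with naproxen, with an exact permutation p of 0.714. A difference between the compounds stays open too and was not tested apart from these.

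Each comparison was set against the other splits of its 8 arrays into 4 and 4, 35 in all with the real one. With 0 probe sets called in each comparison, all 35 splits gave as many by necessity, so these counts decide nothing about chance (highest other 4742 for NO-naproxen, 2195 for naproxen and 1 between the compounds). For naproxen against control, 4 splits gave at least the 1135 past the study's criterion (highest other 2990) and 7 at least the 6 lists (highest other 8), so chance was not excluded for these 2 counts. For NO-naproxen against control the splits with as many were 6 for the 738 (highest other 3967) and 19 for the 3 lists (highest other 15). For NO-naproxen against naproxen they were 23 for the 111 (highest other 1224) and 25 for the 2 lists (highest other 12), and chance was not excluded for these 4 counts either. Splits that call many more probe sets than the real one point to a structure of the arrays: the split with most past the criterion among NO-naproxen and control arrays parted mean interquartile ranges by 0.41 log2 units, against 0.26 in the real one. For the correlation of the fold changes of both treatments, 772 of all 17325 groupings of the 12 arrays gave a value as high as 0.826 (highest other 0.924), a share of 0.0446. With the arrays' spread as a covariate the share was 0.0959, and without the 2 arrays of narrowest spread 0.444, so chance was not excluded there.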

How the results depend on the processing

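Added constants of 1 and 64, the arrays' spread as a covariate and leaving out the 2 arrays of narrowest spread (control replicates 3 and 4) were chosen after seeing the data; the other alternatives were not. All alternatives chosen beforehand were run, and where a value moved below, the cause was not tested unless named. Signal over background limits the 38.0% of probe sets that lay within the olfactory receptor range. Over the named genes, 147 results were run under 2917 settings in all, of which 35 turned in sign, in 10 results, and 4 passed the adjusted threshold newly: Arrdc3 with array weights and without control replicate 2 for NO-naproxen, and Per2 and Rgs16 without control replicate 1 for naproxen. Over 19 list results and 361 settings, 13 turned in sign, 54 missed the threshold and 13 passed it newly.

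Lists past camera numbered 3 for NO-naproxen against control, 6 for naproxen against control and 2 between the compounds, and 0 in each with an estimated correlation and 0 in each with the directional form of fry. Those 3 became 1 after quantile normalization, 0 with array weights and 5 with the arrays' spread as a covariate. The count of 6 became 3 after quantile normalization, 3 without dim probe sets, where fewer genes were tested, and 3 with array weights. These counts take in any list past the threshold. After quantile normalization the Kupffer cell, oxidative phosphorylation, cytochrome P450 and stellate lists missed it, so the 3 include a list outside the 6. Those 2 became 1 with an added constant of 1 and 1 with the arrays' spread as a covariate. Leaving out 1 array gave 0 to 5, 1 to 8 and 1 to 4 lists.

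Probe sets past the adjusted threshold numbered 2 with array weights for NO-naproxen against control, and without 1 array 0 to 4 for NO-naproxen, 0 to 3 for naproxen and 0 between the compounds. Past the study's criterion, NO-naproxen gave 55 at a fold of at least 2, a stricter threshold, 2527 with array weights, 154 with an added constant of 64, which shrinks fold changes, 236 with the arrays' spread as a covariate and 215 without the 2 arrays of narrowest spread. Naproxen gave 88 at a fold of at least 2, 752 without dim probe sets and 747 with 1 probe set per gene, where fewer were tested, 191 with an added constant of 64, 332 with the spread as a covariate and 291 without the 2 arrays. Between the compounds the 111 became 3 at a fold of at least 2, 40 without dim probe sets and 55 with 1 probe set per gene, 304 with array weights, 299 with an added constant of 1 and 8 with one of 64. Leaving out 1 array gave 284 to 2570 for NO-naproxen, 574 to 2973 for naproxen and 98 to 331 between the compounds. The correlation of both treatments' fold changes, 0.826, was 0.747 with an added constant of 1, 0.648 with the spread as a covariate, 0.697 without the 2 arrays, 0.463 with controls split, where no array is shared, and 0.740 to 0.897 without 1 array.

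With the replicate number as a block, 1 list passed for NO-naproxen against control, and 820, 1193 and 120 probe sets passed the criterion for NO-naproxen, for naproxen and between the compounds. Arrays of the same number correlated by -0.382 to 0.481 (mean 0.0194) after group means were removed, and 3 arrays correlated best with their own number.

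The following turned in sign. After quantile normalization A2m with naproxen was 0.067, Cyp1a1 0.013 with naproxen and 0.10 with NO-naproxen, and Hamp -0.058 and the clock list -0.050 with NO-naproxen. After median centring A2m was 0.0032, the cholesterol list 0.0022, the clock list 0.019 and hepatocyte markers 0.091 with naproxen, and Cyp1a1 0.054 with NO-naproxen. With array weights the cell cycle list with NO-naproxen was -0.0048 and Ptgs2 between the compounds -0.046. With the spread as a covariate A2m was 0.086, Cyp1a1 0.0049 and Nos2 0.014 with naproxen, and Cyp1a1 0.16, Hamp -0.12, Lcn2 0.020, Nos2 0.44 and the clock list -0.086 with NO-naproxen. Without the 2 arrays of narrowest spread A2m with naproxen was 0.12, and with NO-naproxen Cyp1a1 was 0.070, Hamp -0.084, Nos2 0.33, the cell cycle list -0.013 and the clock list -0.040. Without 1 array in turn, values with naproxen ranged over -0.40 to 0.17 for A2m, -0.36 to 0.022 for Cyp1a1 and -0.065 to 0.020 for hepatocyte markers. With NO-naproxen they ranged over -0.17 to 0.095 for Cyp1a1, -0.15 to 0.26 for Hamp, -0.60 to 0.021 for Nos2, -0.013 to 0.16 for the cell cycle list and -0.059 to 0.16 for the clock list. Between the compounds they ranged over -0.037 to 0.34 for Cyp1a1, -0.0026 to 0.20 for Ptgs1, -0.072 to 0.22 for Ptgs2 and -0.15 to 0.036 for the cholesterol list.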

Other observations

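All genes named in this part were chosen after their values were seen. Genes of fatty acid and triglyceride synthesis were not called in any comparison in camera. With naproxen against control their mean log2 fold change was -0.16 (camera, adjusted p = 0.0934), with 4 members lower and 1 higher at an unadjusted p under 0.05. These were Acly, which makes cytosolic acetyl-CoA, at -0.43, the pyruvate kinase of liver, Pklr, at -0.43, Gpam at -0.37 and Pnpla3 at -0.93, and Lpin1 at 1.00. With NO-naproxen the mean was -0.01 (adjusted p = 0.704), and the direct difference between the compounds was 0.16 (adjusted p = 0.0991), with the lipogenic regulator Srebf1 at 0.56.

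Targets of NRF2, the regulator of antioxidant genes, had a mean of 0.12 with naproxen (camera, adjusted p = 0.137) and 0.14 with NO-naproxen (adjusted p = 0.293). The aldo-keto reductase Akr1b10 measured 0.83 and 0.77. The cytochrome P450 list, called with naproxen, had a mean of 0.21 with NO-naproxen (adjusted p = 0.143), with Cyp3a2 at 1.13 and Ahr at 0.63, and the difference between the compounds had a mean of 0.01 (adjusted p = 0.672).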
